A study of Caenorhabditis elegans with 54 samples.

How the data were processed

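RNA of 36 labelled samples per age was measured on 54 arrays of 2 colours, 18 for each of the ages 40 h, 96 h and 214 h. Each array compared 1 line labelled with Cy3 with 1 line labelled with Cy5, both of the same age, and there was no common reference sample. Groups were taken from the labels of the developmental stage. The titles name the same 18 pairs of lines at each age, in the same dye orientation, and the protocol says that the dishes of all ages came from the same synchronised eggs. The pair of lines therefore served as a block. After removal of the age means, arrays of the same pair at 40 h and 96 h correlated across genes with a median r of 0.23, against -0.02 for different pairs. The values were 0.25 and -0.01 between 96 h and 214 h, and 0.17 and -0.01 between 40 h and 214 h.

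Per the file headers, the intensity of each spot is the mean foreground and the median local background of each channel as read by the scanner. Per the file headers, percent values give the share of a spot's pixels above its background plus 2 SDs, and the share that was saturated. The authors also deposited a table of log2 ratios of Cy5 over Cy3, normalized within each array with limma, whose version is not given in the sources used here. A loess fit within arrays of the foreground intensities without background correction gave the same values within 0.001 on the log2 scale for 53 of the 54 columns. The column of the 96 h array of WN9 and WN62 differed, with a correlation of 0.886 with its rebuilt values. The authors' column medians lay between -0.0157 and 0.005. No column of the table was left unused.

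The median foreground and background intensities were 253.8 and 160 in Cy3 and 220.5 and 157 in Cy5 at 40 h. They were 227 and 159.5 in Cy3 and 210 and 160.5 in Cy5 at 96 h, and 221.5 and 158.5 in Cy3 and 200.5 and 159.5 in Cy5 at 214 h. A probe counted as clear of background in a channel when at least 50% of its pixels lay above the background plus 2 SDs. Per the file headers' pixel values, the percent of worm probes clear of background ran over arrays from 29.3 to 53 in Cy3 and 35.2 to 56.8 in Cy5 at 40 h. It ran from 26.6 to 57.2 and 36.8 to 57.3 at 96 h, and from 26.5 to 51.1 and 24.3 to 55.1 at 214 h, so that dim genes were measured with low precision at all ages. The LOWESS columns of the scanner software were not used here.

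Of 23232 spots, 742 were controls or empty and 22490 were worm probes. The platform annotation gave a gene to 17447 probes, and sequence names and the annotation together matched 21378 probes to a gene of the WBcel235 reference. The annotation and the sequence name disagreed for 35 probes, which kept the name in the file, and 1077 probes had no match. The reference served for gene names and for the order of genes along chromosomes, and the build behind the probe design is not given in the sources used here.

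The main values came from the scanner intensities, since age differs only between arrays. Background was corrected by normexp with an offset of 50, ratios by loess within arrays with control spots at weight 0, and mean log2 intensities between arrays by quantiles (R 4.3.3, limma 3.58.1, statmod 1.5.0). Probes clear of background in either channel on fewer than 18 arrays were left out. Of several probes of a gene, the one with the highest mean intensity was kept, which left 10966 genes. Genes with more than 1 tested probe numbered 1047, and their probes were called in opposite directions in 34 cases from 40 h to 96 h, 22 from 96 h to 214 h and 48 from 40 h to 214 h. A called gene that was not clear of background on any array of 1 age, or was saturated on all, was given a bound in place of a fold. Bounds applied to 257 calls from 40 h to 96 h, 70 from 96 h to 214 h and 237 from 40 h to 214 h. The bound replaced each channel's value by the lowest normalized value among probes clear of background on that array, which lay between 5.61 and 8.21 (log2).

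Ages were compared by limma on the mean log2 intensity of each array, with the pair of lines as a fixed block and Benjamini-Hochberg adjusted p at 0.05. Spread between lines was compared by limma on the absolute deviation of each log2 ratio from its mean at that age, which holds line differences and array noise together. Lasting line differences were sought by an F test of the 18 pair means, with age as a fixed effect. The median log2 ratio of SDs was set against 100 draws with ages permuted within pairs, and the median correlation between ages against 100 draws with pairs exchanged, the real one included. The 28 gene lists were written from textbook knowledge, and were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Adjustment ran over 84 tests of lists. Two-sided Fisher's exact tests set the share of lasting differences in each list against all tested genes. The lists, tests, groups and the rule for named genes were fixed before the data were examined.

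The genes named for each age comparison were those called, with a gene name, changed the same way in at least 17 of 18 pairs and with a mean intensity at the higher age above the median of 8.72 (log2). Of these the 12 with the largest rise and the 12 with the largest fall were taken. From each list up to 4 called members with the largest change were eligible. The 10 genes with the largest difference in spread each way and the 20 genes with the highest F were also named.

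The fits were tested on simulated data with the spread of the real genes. Genes were drawn independently of each other from normal distributions, with the same SD at all ages unless stated. Real genes vary together and their SDs can differ with age, so that the counts of unchanged genes called need not hold there. For 214 h against 40 h, 57 of 100 genes changed by 0.5 on the log2 scale and 100 of 100 changed by 1 were recovered, and 5 unchanged genes were called. For 96 h against 40 h, where no gene was changed, limma called 0 genes. An SD 3 times larger at 214 h was recovered for 145 of 200 genes, with 6 others called, and pair means with 2 times the residual SD for 199 of 200 genes, with 16 others called.

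Arrays were scanned on 9 days, with arrays of all ages on each. Within single days, between 83.2% and 98.7% of the called genes changed in the same direction as over all arrays. Results were recomputed with scan day as the block and without the pair block. Other alternatives were no background correction, centring in place of quantiles or loess, a common scale of ratios, no filter and a strict filter (both channels of all 54 arrays clear of background), separate channels, every probe, array weights, a fold of at least 2, an F test of variances, each age left out, and the authors' log ratios. The pairs with doubtful labels (WN19/WN39, WN19/WN1 and WN44/WN2) were left out together, and so was the pair WN76/WN59 alone. The Cy3 line of WN44/WN2 is WN44 in the titles but WN54 in the source names. The genotypes of the lines were not used here.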

Results

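Whole-animal RNA of recombinant inbred lines of the nematode Caenorhabditis elegans was measured at 3 ages on 54 arrays. Each line is an inbred mosaic of the genomes of the strains N2 and CB4856, and each array carried 1 line in the Cy3 channel and another in the Cy5 channel. The same 18 pairs of lines were hybridised at 40 h of culture (late L3 larvae), at 96 h (the end of the reproductive period) and at 214 h (old adults). Each age thus had 18 arrays and 36 labelled samples. Worms grew at 24 °C. The adults of both later ages had spent 30 h from hour 41 on dishes with the DNA synthesis inhibitor FUDR, which prevents offspring, and the larvae had not. Comparisons with 40 h therefore cannot tell age from FUDR. The samples of 96 h and 214 h had the same exposure but differ in the time since it, which cannot be told from age. On average 44% of the worm probes in Cy3 and 49.8% in Cy5 stood clear of background at 40 h, against 43.9% and 46.2% at 96 h and 41% and 41.9% at 214 h. The comparisons ask how expression changes from larvae to old adults, how far the lines differ at each age, and which line differences show in the mean over the 3 ages. The number of arrays limits the precision. The limma p-values set differences against the spread between these arrays that age and pair of lines leave.

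From 40 h to 96 h, which also differ in FUDR, most cuticle collagen genes fell and most genes of oocytes and cell division rose. The cuticlin gene cut-2 fell 39.3-fold (log2 change -5.30 ± 0.24 SE, n = 18 pairs). The collagen genes col-130 (37-fold), col-176 (35.1-fold), col-12 (34.7-fold), sqt-1 (33.8-fold), col-17 (33.7-fold), col-39 (31.6-fold) and col-107 (31-fold) fell with it. Y48G8AL.12, C02E7.7, C02E7.6 and E01G4.6 fell between 31.6-fold and 37.5-fold. Among the genes that rose, skr-7, a Skp1-related component of ubiquitin ligases, was 36.8-fold higher at 96 h (5.20 ± 0.19 SE) and the chitinase gene cht-1 28.1-fold (4.81 ± 0.23 SE). C01G6.3 rose 22.1-fold, F48C1.9 21.3-fold, the transthyretin-like gene ttr-50 19.9-fold and the metal-responsive gene numr-1 19.5-fold. D1086.1 (18.8-fold), the cytochrome P450 gene cyp-14A5 (18.6-fold), the glutathione S-transferase gene gst-24 (16.6-fold) and F08G2.5 (16.3-fold) followed. The caveolin gene cav-1 and the C-type lectin gene clec-266 were not well above background on any array at 40 h, and rose at least 25.9-fold and by at least 3.62 on the log2 scale. Each of these genes moved the same way in 18 of 18 pairs of lines (largest adjusted p = 1.57e-17, limma with Benjamini-Hochberg adjustment).

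All 26 measured eggshell and oocyte genes rose from 40 h to 96 h, with a median of 1.57 on the log2 scale relative to the median of all genes. They were led by perm-2 (6.32-fold), the maternal RNA-binding protein genes mex-6 (4.81-fold) and pos-1 (4.41-fold) and the eggshell proteoglycan gene cpg-3 (4.61-fold). Camera, a test of a list against all other genes, gave an adjusted p = 1.57e-08, and an adjusted p = 0.205 with an estimated correlation. Every one of 28 DNA replication genes rose (relative median 0.80), among them rnr-2, the small subunit of ribonucleotide reductase (3.71-fold), and pcn-1, which encodes PCNA (2.89-fold). Their adjusted p = 9.75e-07 became adjusted p = 0.121 with an estimated correlation. Of 20 mitosis genes 19 rose, with the cyclin genes cyb-2.1 (4.05-fold) and cyb-1 (2.91-fold) first (adjusted p = 0.000163, or adjusted p = 0.117 with an estimated correlation). Of 20 meiosis genes 16 rose, led by spo-11, which makes meiotic double-strand breaks (2.94-fold; adjusted p = 0.00971, or adjusted p = 0.286 with an estimated correlation). Sperm genes went the other way, with 31 of 33 falling and none rising (relative median -2.51). Among them ssp-34 fell 9.04-fold, ssp-19 8.30-fold and the major sperm protein gene msp-45 8.15-fold (adjusted p = 3.63e-12, or adjusted p = 0.143 with an estimated correlation). Of 155 F-box and MATH genes, a family of substrate adaptors of ubiquitin ligases, 114 rose and 14 fell (relative median 0.45). The gene fbxa-163 was at least 4.78-fold and btb-6 6.65-fold higher (adjusted p = 1.4e-06, or adjusted p = 0.117 with an estimated correlation).

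Of 98 genes named col, 78 fell and 11 rose between 40 h and 96 h (relative median -2.48; adjusted p = 1.01e-18, or adjusted p = 0.139 with an estimated correlation). Collagens named for body shape fell in 16 and rose in 2 of 18 cases, dpy-13 by 28.5-fold and dpy-4 by 27.6-fold (adjusted p = 5.07e-09, or adjusted p = 0.117 with an estimated correlation). Moulting genes fell in 14 and rose in 1 of 19 cases, mlt-10 by 14.4-fold and qua-1 by 12.7-fold (adjusted p = 1.03e-06, or adjusted p = 0.117 with an estimated correlation). Muscle genes fell in 26 and rose in 2 of 31 cases, with the troponin I gene tni-1 5.93-fold and the pharyngeal myosin gene myo-2 4.49-fold lower (adjusted p = 1.03e-06, or adjusted p = 0.229 with an estimated correlation). Intestinal genes fell in 15 and rose in 2 of 25 cases, the protease gene cpr-5 by 16.9-fold and the peptide transporter gene pept-1 by 8.16-fold (adjusted p = 0.000244, or adjusted p = 0.249 with an estimated correlation). Respiratory chain genes fell in 21 and rose in 1 of 36 cases, with mev-1, a subunit of succinate dehydrogenase, 2.38-fold lower (adjusted p = 0.0026, or adjusted p = 0.135 with an estimated correlation). Neuronal genes fell in 15 and rose in 4 of 24 cases, ida-1 by 3.80-fold and the touch neuron gene mec-17 by 2.66-fold (adjusted p = 0.0207, or adjusted p = 0.272 with an estimated correlation).

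The other lists had no camera call between 40 h and 96 h. Of 6 vitellogenin genes, which encode yolk proteins, 5 rose, vit-2 by 2.42-fold. Innate immunity genes rose in 20 and fell in 4 of 38 cases, with sysm-1 8.61-fold and the lysozyme gene lys-7 5.86-fold higher and lys-4 11.1-fold lower. Of 19 DAF-16 targets 9 rose, the metallothionein gene mtl-1 8.44-fold and dod-3 7.48-fold, and 4 fell. The counts of members higher and lower were 25 and 17 of 56 for C-type lectins, 36 and 21 of 79 for cytochrome P450 and glucuronosyltransferase genes, and 15 and 11 of 39 for antioxidant and phase II genes. They were 5 and 2 of 12 for heat shock genes, with the small heat shock protein gene sip-1 3.26-fold higher. Chaperones of the endoplasmic reticulum and mitochondria gave 1 and 9 of 18, with hsp-60 2.19-fold lower, the proteasome 3 and 2 of 31, and ribosomal proteins 5 and 7 of 64. Histones gave 10 and 13 of 32, fatty acid metabolism 11 and 14 of 35, and neuropeptides 9 and 15 of 41, with the insulin-like gene ins-7 5.36-fold higher. Chemoreceptors gave 18 and 17 of 54 and heterochronic genes 1 and 1 of 5.

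Across 10966 genes tested, 4649 were higher and 3400 lower at 96 h than at 40 h, and 1384 and 1397 of them differed at least 2-fold. With arrays centred on their medians in place of quantile scaling, the share of higher calls went from 57.8% to 70.4%, and the median change of all genes from 0.13 to 0.37. List medians are therefore given relative to the median of all genes, and no list with a camera call changed its direction on that scale with centring or without background correction. Of the lists without a call, the proteasome (-0.06 to 0.02) and the cytochrome P450 and glucuronosyltransferase genes (0.04 to -0.06) changed sign with centring. The latter (0.04 to -0.01) and C-type lectins (-0.0003 to 0.0024) also did so without background correction. Within the 9 scan days, between 91.8% and 98.7% of the called genes moved the same way. The list medians, as they stand, ran over scan days from 0.99 to 2.14 for eggshell and oocyte genes, from -4.12 to -1.32 for sperm genes and from -2.95 to -2.05 for col genes. Adjusted over the list alone, the counts were 12 higher and 79 lower for col genes, 1 and 15 for moulting, 1 and 3 for ribosomal proteins and 1 and 20 for respiration. They were 2 and 2 for the proteasome, 9 and 14 for neuropeptides and 115 and 14 for F-box and MATH genes, and for every other list they equalled those over all genes. As they stand, the medians of ribosomal proteins, the proteasome, antioxidant genes, chemoreceptors and histones were positive while the camera direction was down, with a negative mean for chemoreceptors and histones. Relative to all genes these medians were negative, like the camera direction. The relative median of C-type lectins (-0.0003) went against its camera direction, up. None of these lists was called.

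**Figure D1:**
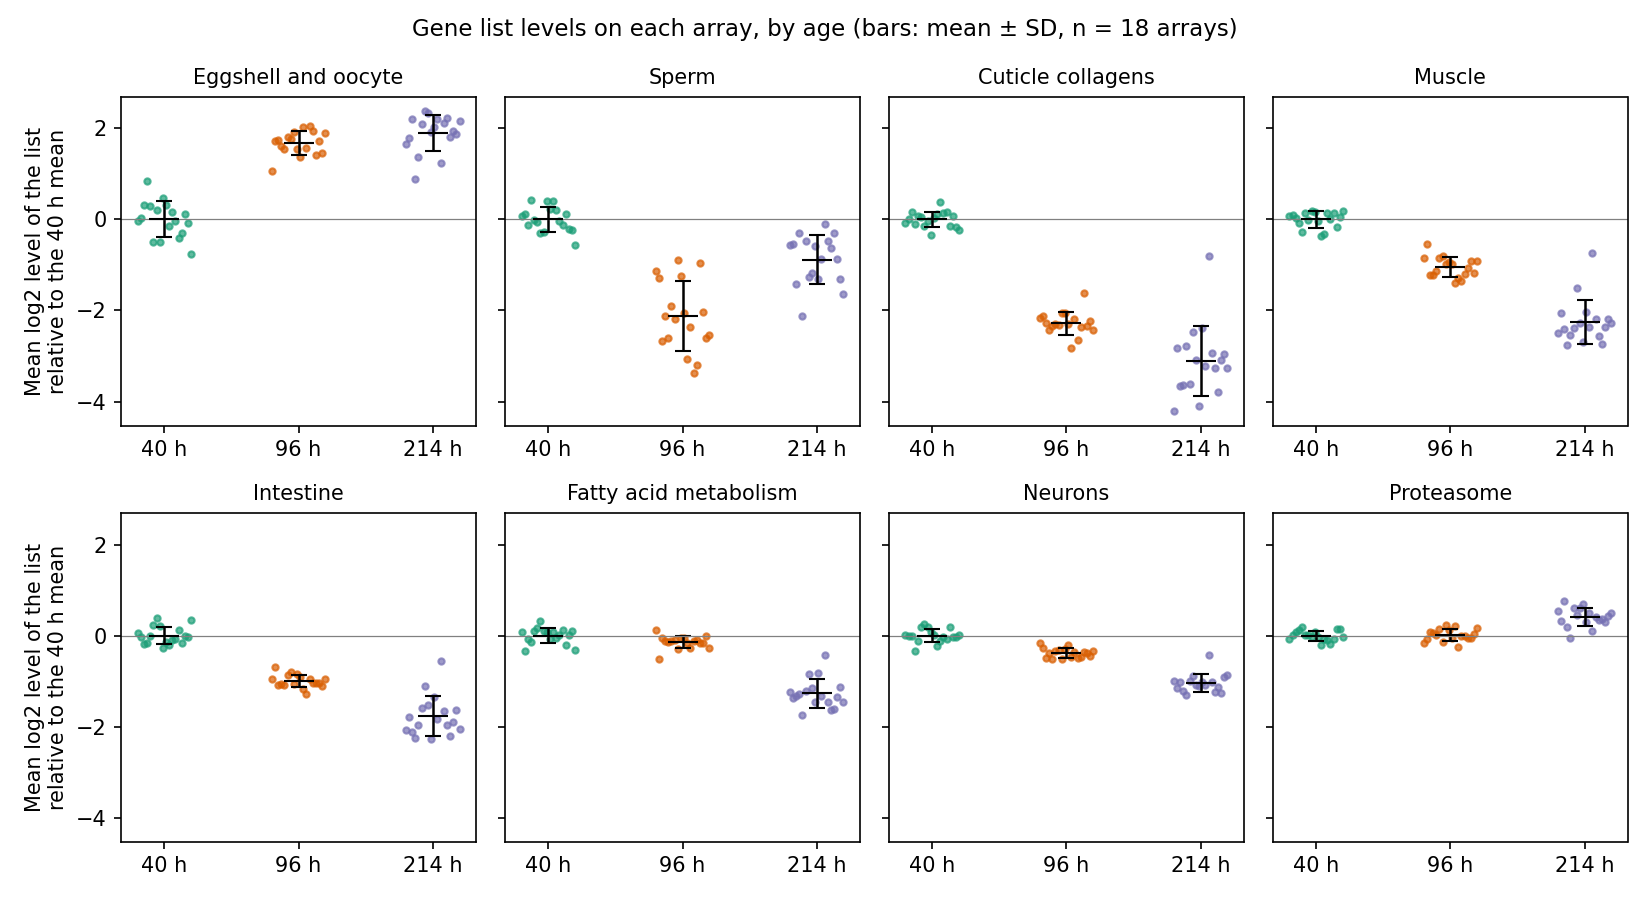
Mean log2 level of gene lists on each of the 54 arrays, relative to the mean at 40 h, against age. Points are arrays and bars mark the mean ± SD of 18 arrays; eggshell and oocyte genes stay high after 40 h, sperm genes are lowest at 96 h, and muscle and intestine genes are lowest at 214 h.

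From 96 h to 214 h sperm genes rose again, while genes of muscle, intestine, fat metabolism and detoxification fell. The major sperm protein genes msp-49 and msp-142 were 4.43-fold (log2 change 2.15 ± 0.23 SE, n = 18 pairs) and 3.93-fold higher at 214 h, and spch-3, which encodes a basic protein of sperm chromatin, 4.30-fold. R09E10.6 (4.23-fold), the BTB-MATH gene bath-36 (4.16-fold), msrp-2 (4.04-fold), nspe-7 (3.96-fold) and gipc-1 (3.88-fold) rose too. C46A5.6 (3.79-fold), Y37D8A.5 (3.78-fold), W03D8.10 (3.73-fold) and T28H11.7 (3.70-fold) followed. The genes with the largest falls were the glucuronosyltransferase gene ugt-26 (log2 change -3.62 ± 0.17 SE), gst-24 (11.3-fold), the lectin gene clec-52 (11.2-fold), C34H4.1 (10.4-fold) and the acid phosphatase gene acp-6 (9.88-fold). The collagen genes col-140 (9.18-fold), col-101 (8.93-fold), col-178 (8.87-fold), col-119 (8.42-fold) and col-8 (8.15-fold) fell next to F21C10.10 (8.95-fold) and C17H12.8 (8.82-fold). Each of these genes moved the same way in at least 17 of 18 pairs (largest adjusted p = 2.36e-08, limma).

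Of 33 sperm genes 29 were higher at 214 h than at 96 h and none was lower (relative median 1.40; adjusted p = 4.91e-08, or adjusted p = 0.249 with an estimated correlation). The list's own median was 0.35 on 1 scan day and 3.31 on another, and 27 of the 33 genes were lower at 214 h than at 40 h. Meiosis genes rose in 19 of 20 cases (relative median 0.78), with dsb-1 2.25-fold and the synaptonemal complex gene syp-1 2.18-fold higher (adjusted p = 1.4e-06, or adjusted p = 0.117 with an estimated correlation). DNA replication genes rose in 19 of 28 cases, rfc-4 by 1.98-fold (adjusted p = 0.00253, or adjusted p = 0.33 with an estimated correlation). Mitosis genes rose in 12 of 20 cases, ndc-80 by 1.68-fold (adjusted p = 0.0146, or adjusted p = 0.271 with an estimated correlation). Proteasome genes rose in 22 of 31 cases and fell in none, with rpt-3 1.69-fold and pas-7 1.63-fold higher (relative median 0.30; adjusted p = 0.00246, or adjusted p = 0.205 with an estimated correlation).

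Fatty acid metabolism fell from 96 h to 214 h in 31 of 35 genes (relative median -1.03), the acyl-CoA dehydrogenase gene acdh-1 by 8.82-fold and the desaturase gene fat-5 by 4.29-fold (adjusted p = 4.13e-09, or adjusted p = 0.0643 with an estimated correlation). Cytochrome P450 and glucuronosyltransferase genes fell in 61 and rose in 7 of 79 cases, with cyp-14A5 5.98-fold lower (adjusted p = 3.91e-11, or adjusted p = 0.0622 with an estimated correlation). C-type lectins fell in 40 and rose in 8 of 56 cases, clec-1 by 6.74-fold (adjusted p = 7.95e-08). Theirs was the only one of the 46 camera calls made over the 3 age comparisons that held with an estimated correlation (adjusted p = 0.0276). Muscle genes fell in 23 and rose in 1 of 31 cases (relative median -1.25), with the body wall myosin gene unc-54 6.29-fold and the troponin I gene unc-27 6.01-fold lower (adjusted p = 8.02e-08, or adjusted p = 0.184 with an estimated correlation). Intestinal genes fell in 18 and rose in 3 of 25 cases, ifc-2 by 3.95-fold (adjusted p = 0.00012, or adjusted p = 0.232 with an estimated correlation). Innate immunity genes fell in 24 and rose in 4 of 38 cases, lys-2 by 7.34-fold and irg-7 by 5.89-fold (adjusted p = 7.43e-05, or adjusted p = 0.25 with an estimated correlation). Neuropeptide genes fell in 33 and rose in 2 of 41 cases, flp-14 by 2.60-fold (adjusted p = 6.64e-07, or adjusted p = 0.0684 with an estimated correlation). Neuronal genes fell in 19 of 24 cases, the decarboxylase gene bas-1 by 2.97-fold (adjusted p = 3.19e-05, or adjusted p = 0.117 with an estimated correlation). DAF-16 targets fell in 13 and rose in 2 of 19 cases, including the gluconeogenic gene pck-1 by 3.51-fold and the glyoxylate cycle gene icl-1 by 3.45-fold (adjusted p = 0.0012, or adjusted p = 0.117 with an estimated correlation).

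Antioxidant and phase II genes fell in 20 and rose in 5 of 39 cases, gst-4 by 3.97-fold (adjusted p = 0.0116, or adjusted p = 0.189 with an estimated correlation). Col genes fell in 43 and rose in 7 of 98 cases, with medians from -1.25 to 0.71 on single scan days (adjusted p = 6.87e-05, or adjusted p = 0.577 with an estimated correlation). Among lists without a call between 96 h and 214 h, eggshell and oocyte genes had 8 higher and 2 lower of 26, and vitellogenins 3 lower of 6, vit-1 by 3.04-fold. Ribosomal protein genes were higher in 12 and lower in 2 of 64 cases, and heat shock genes in 6 and 2 of 12. Respiration genes were higher in 8 and lower in 6 of 36 cases, where the ATP synthase genes asb-1 and asb-2 went opposite ways, 2.03-fold up and 2.22-fold down. In all, 3938 genes were higher and 3442 lower at 214 h than at 96 h, 523 and 1111 of them at least 2-fold. Between 83.2% and 98.5% of the called genes moved the same way within the 9 scan days. Adjusted over the list alone, the counts were 5 higher and 2 lower for eggshell and oocyte genes, 20 and 0 for meiosis, 2 and 5 for moulting and 8 and 2 for ribosomal proteins. They were 7 and 6 for respiration, 5 and 24 for immunity and 7 and 62 for cytochrome P450 and glucuronosyltransferase genes. On the relative scale the eggshell list changed sign with centring (0.16 to -0.002), and the body shape collagens without background correction (-0.06 to 0.002). As they stand, the medians of body shape collagens and of chaperones of the endoplasmic reticulum and mitochondria were positive, with a negative mean and camera direction. Their relative medians were negative too (-0.06 and -0.05). Respiration had a negative median, relative median and mean but a positive camera direction. Ribosomal proteins had a negative relative median (-0.03) but a positive camera direction. None of these lists was called.

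Between 40 h and 214 h, the span from larvae to old adults, collagen genes fell most. The largest falls were those of col-176 (40.8-fold, log2 change -5.35 ± 0.27 SE, n = 18 pairs), col-34 (36.9-fold), col-39 (32.9-fold), sqt-1 (32.6-fold) and col-12 (32-fold). The collagen genes col-107 (29.8-fold), col-117 (29.2-fold), dpy-13 (28.2-fold) and dpy-4 (27.4-fold) followed, together with E01G4.6 (29.8-fold), R12E2.14 (29.2-fold) and cut-2 (28.5-fold). The genes with the largest rises were F48C1.9 (16.7-fold, log2 change 4.06 ± 0.27 SE), C01G6.3 (12.1-fold), ule-1 (10.6-fold), cht-1 (10.5-fold) and R04D3.4 (9.61-fold). The lysozyme gene ilys-3 (8.32-fold), skr-7 (8.30-fold), T12G3.6 (8.05-fold) and numr-1 (8.02-fold) followed. Not well above background on any array at 40 h, dct-7 rose at least 14.4-fold, cav-1 at least 10.8-fold and clec-266 at least 8.76-fold. Each of these genes moved the same way in 18 of 18 pairs (largest adjusted p = 2.26e-12, limma).

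Muscle genes were lower at 214 h than at 40 h in 28 and higher in 3 of 31 cases (relative median -2.96), with unc-54 12.4-fold, tnt-2 11.9-fold and the perlecan gene unc-52 11.3-fold lower (adjusted p = 5.32e-10, or adjusted p = 0.121 with an estimated correlation). Intestinal genes were lower in 23 of 25 cases, the intermediate filament gene ifb-2 by 12.4-fold (adjusted p = 1.13e-07, or adjusted p = 0.117 with an estimated correlation). Fatty acid genes were lower in 27 and higher in 5 of 35 cases, acdh-1 by 24.1-fold and elo-5 by 7.34-fold (adjusted p = 1.94e-05, or adjusted p = 0.117 with an estimated correlation). Neuronal genes were lower in 19 and higher in 4 of 24 cases, ida-1 by 10.3-fold and the tubulin gene mec-7 by 5.53-fold (adjusted p = 9.84e-05, or adjusted p = 0.117 with an estimated correlation). Neuropeptide genes were lower in 31 and higher in 5 of 41 cases, ins-35 by 5.40-fold (adjusted p = 0.000151, or adjusted p = 0.117 with an estimated correlation). C-type lectins were lower in 39 and higher in 13 of 56 cases, clec-45 by 13.2-fold (adjusted p = 0.000718, or adjusted p = 0.117 with an estimated correlation). Moulting genes were lower in 17 and higher in 2 of 19 cases (adjusted p = 4.31e-06, or adjusted p = 0.117 with an estimated correlation). Col genes fell in 93 and rose in 2 of 98 cases (adjusted p = 9.56e-25, or adjusted p = 0.117 with an estimated correlation) and body shape collagens fell in 16 and rose in 2 of 18 (adjusted p = 1.5e-07, or adjusted p = 0.121 with an estimated correlation). Sperm genes were lower in 27 and higher in 2 of 33 cases, ssp-10 by 5.08-fold (adjusted p = 0.00187, or adjusted p = 0.595 with an estimated correlation). Cytochrome P450 and glucuronosyltransferase genes were lower in 49 and higher in 18 of 79 cases, ugt-46 by 8.76-fold (adjusted p = 0.00168, or adjusted p = 0.243 with an estimated correlation). Respiration genes were lower in 19 and higher in 6 of 36 cases, asg-2 by 4.28-fold (adjusted p = 0.0468, or adjusted p = 0.286 with an estimated correlation).

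The lists of eggshell and oocyte, DNA replication, meiosis and mitosis genes stayed above their larval level. All 26 eggshell and oocyte genes were higher at 214 h than at 40 h, egg-4 by 5.62-fold (adjusted p = 7.5e-08, or adjusted p = 0.229 with an estimated correlation). So were all 28 DNA replication genes, rnr-2 by 4.85-fold (adjusted p = 6.9e-08, or adjusted p = 0.117 with an estimated correlation). All 20 meiosis genes were higher, syp-1 by 3.67-fold (adjusted p = 1.52e-06, or adjusted p = 0.117 with an estimated correlation), and all 20 mitosis genes, cyb-2.1 by 4.94-fold (adjusted p = 1.44e-05, or adjusted p = 0.117 with an estimated correlation). F-box and MATH genes were higher in 109 and lower in 24 of 155 cases, bath-36 by 7.66-fold (adjusted p = 1.06e-05, or adjusted p = 0.139 with an estimated correlation). Among lists without a call, proteasome genes were higher in 22 and lower in none of 31 cases, and heat shock genes were higher in 6 and lower in 1 of 12, hsp-70 by 3.39-fold. In all, 4952 genes were higher and 4051 lower at 214 h than at 40 h, 2229 and 1986 of them at least 2-fold, and centring took the share of higher calls from 55% to 61.5%. Between 92.7% and 97.7% of the called genes moved the same way within scan days, where the muscle median ran from -3.28 to -1.54 and the eggshell median from 1.09 to 2.58. Adjusted over the list alone, the counts were 7 higher and 3 lower for ribosomal proteins, 6 and 18 for respiration and 20 and 0 for the proteasome. Fry, which tests whether the genes of a list move one way on balance, called 21 lists from 40 h to 96 h, 20 from 96 h to 214 h and 26 over the whole span. Chemoreceptors, without a camera call, had a positive median but a negative mean and camera direction, and their relative median went from 0.02 to -0.16 with centring. The Cy3 sample labelled WN76 at 214 h lay at 0.08 on an axis from the mean of 40 h (0) to the mean of 214 h (1), where the Cy5 sample of the same array, WN59, lay at 0.717 and every other sample of 214 h at 0.851 or above. Without its pair of lines, WN76/WN59, 4981 genes were higher and 4083 lower.

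**Figure D2:**
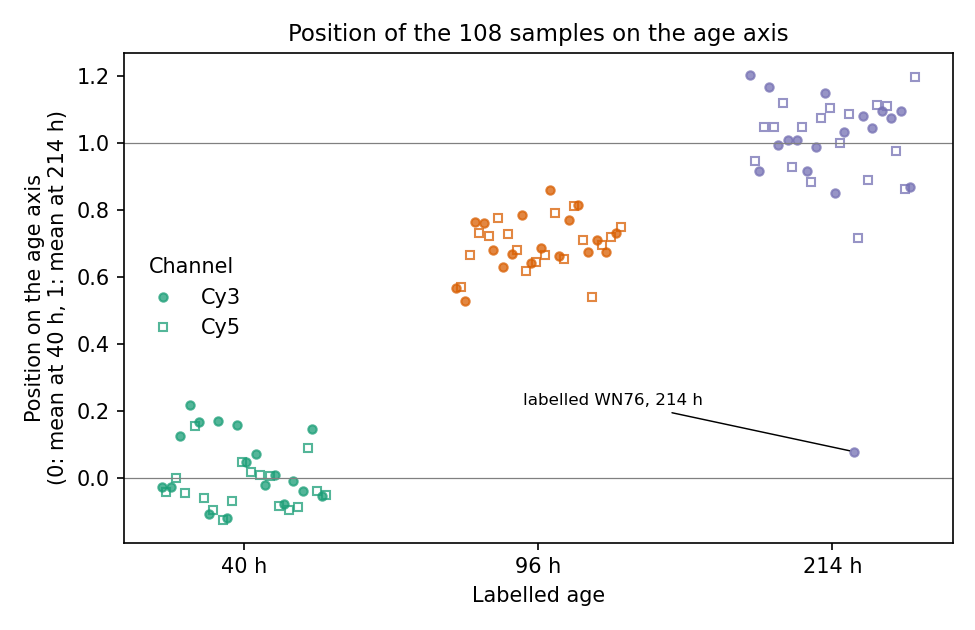
Position of each sample on an axis through the mean expression at 40 h (0) and at 214 h (1), without units, by labelled age. Filled circles are Cy3 and open squares Cy5 samples; 1 sample labelled 214 h, WN76, lies at 0.08 among the 40 h samples, which span -0.125 to 0.218.

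The spread between lines was measured as the deviation of each array's log2 ratio of both lines from its mean at that age. Some muscle, intestine and collagen genes were more spread in old adults than in larvae, and some eggshell and oocyte genes less, and no list was tested for spread as a set. Of 31 muscle genes 20 were more spread and 1 was less spread at 214 h than at 40 h, the median SD of the list going from 0.28 to 1.00. Intestinal genes were more spread in 13 of 25 cases (median SD 0.31 and 1.10), col genes in 36 of 98 (0.62 and 1.42), innate immunity genes in 13 of 38 (0.73 and 1.30) and fatty acid genes in 12 of 35 (0.40 and 0.83). Of 26 eggshell and oocyte genes 19 were less spread and none more (1.12 and 0.53). The more spread lists were also lower in level at 214 h than at 40 h. Their relative medians were -2.96 (muscle), -1.71 (intestine), -3.36 (col), -0.74 (immunity) and -1.32 (fatty acid genes), against 1.88 for the eggshell list. Moulting (-2.08) and neuronal genes (-1.14) were lower too, with 0 and 1 genes more spread. Whether spread follows level in these lists was not tested. The SD of col-39 went from 0.36 to 2.34, of col-12 from 0.37 to 2.36, of col-94 from 0.24 to 2.25, of rol-6 from 0.47 to 2.27 and of col-147 from 0.45 to 2.13. F41F3.3 (0.38 to 2.48), F54D10.7 (1.19 to 3.05), T02G5.10 (1.41 to 3.17) and C02E7.6 (0.48 to 2.18) were more spread too. Less spread at 214 h were R03H10.6 (3.06 to 0.94), T24A6.16 (2.40 to 0.74), K06H6.2 (1.93 to 0.21), C36C5.14 (2.09 to 0.57) and ZC404.7 (2.19 to 0.85, or 0.28 at 214 h without the WN76/WN59 pair). The genes sdz-24 (2.33 to 0.49), nspa-8 (3.55 to 2.26), Y71G12B.18 (1.96 to 0.33), C39B5.10 (2.97 to 1.55) and ZK1025.5 (1.62 to 0.23) were less spread as well. In all, 914 of 10966 genes were more and 372 less spread at 214 h than at 40 h (limma on absolute deviations). Without the WN76/WN59 pair the counts were 772 and 596, with 17 muscle, 11 intestinal and 32 col genes more spread, and with the age changes regressed out of each array's log ratios they were 285 and 189.

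Of 26 eggshell and oocyte genes, 15 were less spread at 96 h than at 40 h (median SD 0.48 against 1.12). A few genes were more spread at 96 h than at either other age. Among them were C29F9.14 (SD 1.79 at 40 h, 4.23 at 96 h and 2.16 at 214 h), pals-23 (1.59, 3.62 and 1.74) and pals-24 (0.88, 2.77 and 0.92). The genes grsp-4 (1.03, 2.73 and 1.39), T20D4.7 (1.35, 2.95 and 1.46) and the F-box gene fbxa-60 (0.85, 2.50 and 1.31) did likewise. Compared with 40 h, 123 genes were more and 261 less spread at 96 h. Compared with 96 h, 447 were more and 92 less spread at 214 h, including 14 muscle, 10 intestinal and 20 col genes that were more spread. Without the WN76/WN59 pair these were 308 and 79, and 13, 7 and 11. With median centring of the ratios 141 genes were more and 57 less spread, and with the age changes regressed out 103 and 67. Over all genes the median SD of the log2 ratio was 0.352 at 40 h, 0.337 at 96 h and 0.414 at 214 h. The median over genes of the log2 ratio of their SDs was 0.30 for 214 h over 96 h and 0.27 for 214 h over 40 h, values that 2 and 4 of 100 draws with ages permuted within pairs matched, the real one included. For 96 h over 40 h it was -0.01 (99 of 100). With median centring the ratio of 214 h over 40 h was 0.55 and that of 96 h over 40 h 0.31 (permutation p = 0.01 and 0.15). Within scan days the ratios were 0.37, 0.21 and -0.14. Both calls ended without the WN76/WN59 pair (0.18, permutation p = 0.13, and 0.17, permutation p = 0.07). They also ended without background correction, without the filter on dim probes, with a stricter one and without the pairs with doubtful labels, the first also with median centring and the second with the authors' log ratios.

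**Figure D3:**
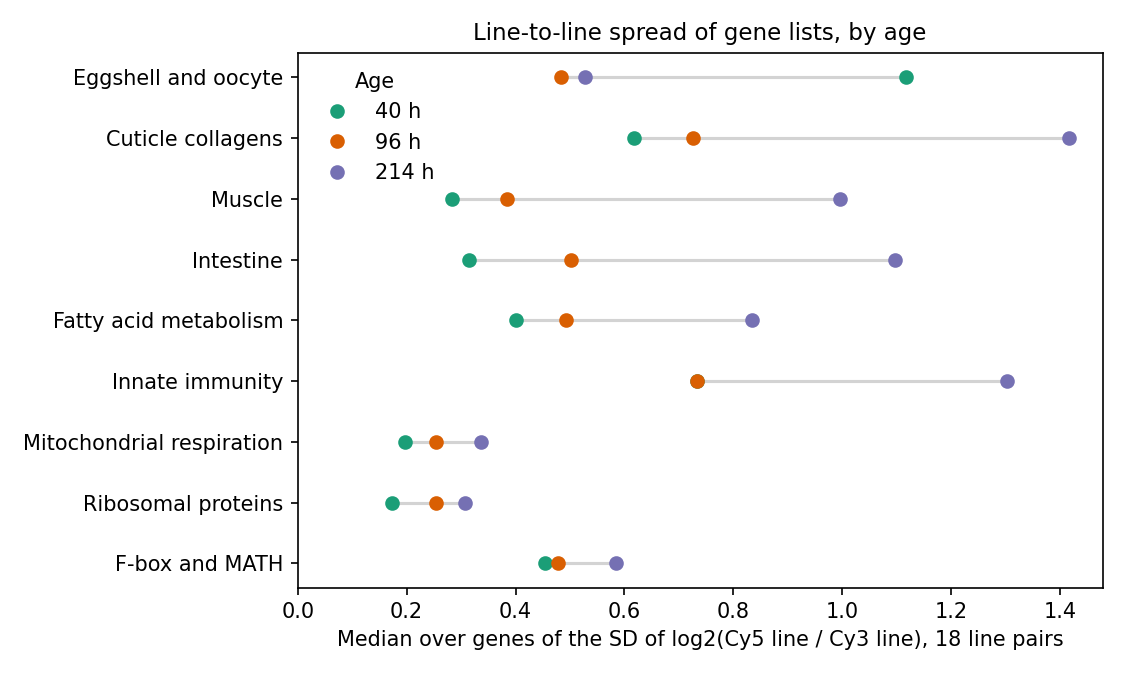
Median over the genes of each list of the SD, across 18 line pairs, of log2(Cy5 line / Cy3 line), by age (coloured points). Muscle, intestine and cuticle collagen genes have their largest value at 214 h (1.00, 1.10 and 1.42), and eggshell and oocyte genes at 40 h (1.12).

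Line differences that lasted from larva to old adult were found for 676 of 10966 genes (6.16%), by an F test of the 18 pair means against the spread within pairs over age, and 1851 genes passed before adjustment. The highest F, 50.2, belonged to F54E2.1, whose pair means ran from -5.34 to 5.99 on the log2 scale and whose values correlated between ages over the 18 pairs with r from 0.93 to 0.98. The F-box gene fbxa-64 (F 49.8), F19B2.5 (48.6), C38D9.2 (36.6), F12A10.2 (36.1) and the checkpoint kinase gene chk-1 (35.6) came next. F15D4.5 and F59E12.6 (34.1 each), pud-2.1 (30), the BTB-MATH gene bath-28 (28.9), pud-2.2 and C27C7.1 (27.5 each), gst-27 (27.4) and F56A8.4 (26) followed. The translation initiation factor genes ife-5 (25.8) and eif-3.H (25.5), F16H6.10 (25), bath-27 (24.5), fbxa-65 (24.4) and puf-6 (24) completed the first 20. All 20 had an r of 0.83 or above between each pair of ages (largest adjusted p = 1.64e-12, limma).

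Of the F-box and MATH genes 50 of 155, or 32.3%, had lasting line differences (odds ratio 7.74, adjusted p = 5e-22, Fisher's exact test over 28 lists). So had 14 of 79 cytochrome P450 and glucuronosyltransferase genes (odds ratio 3.33, adjusted p = 0.00414), whereas none of 98 col genes had them (adjusted p = 0.0423). The ratios of col genes had a large SD at 214 h (median 1.42, against 0.414 over all genes). Whether this hides lasting differences of col genes from the F test was not tested. Fisher's test counts genes as independent. Lasting genes at most 5 genes apart tended to differ between the same lines (median absolute r 0.781), so that these p-values can be too small. Chemoreceptors (8 of 54, adjusted p = 0.118), DAF-16 targets (4 of 19, adjusted p = 0.143), antioxidant genes (6 of 39, adjusted p = 0.143) and C-type lectins (7 of 56, adjusted p = 0.291) had more than the share of all genes without passing the test. Over all genes, the median correlation of line differences was 0.05 between 40 h and 96 h, 0.04 between 96 h and 214 h and 0.21 between 40 h and 214 h. Of 100 draws with pairs exchanged between ages 29, 52 and 1 gave values as large, the real one included. A sequence difference under a probe, or hybridisation of a related gene, gives a lasting difference too and is not separated from expression here. Nor does the F test separate line from egg batch and scan day. The dishes of all ages came from the same eggs, and most pairs were scanned on the same day at all ages. With a strict filter on dim probes, which left 2622 genes, 77 genes had lasting differences and 0 lists passed, without the WN76/WN59 pair 2 lists passed in place of 3, and without the arrays of 40 h, 96 h or 214 h the genes numbered 230, 291 and 375.

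**Figure D4:**
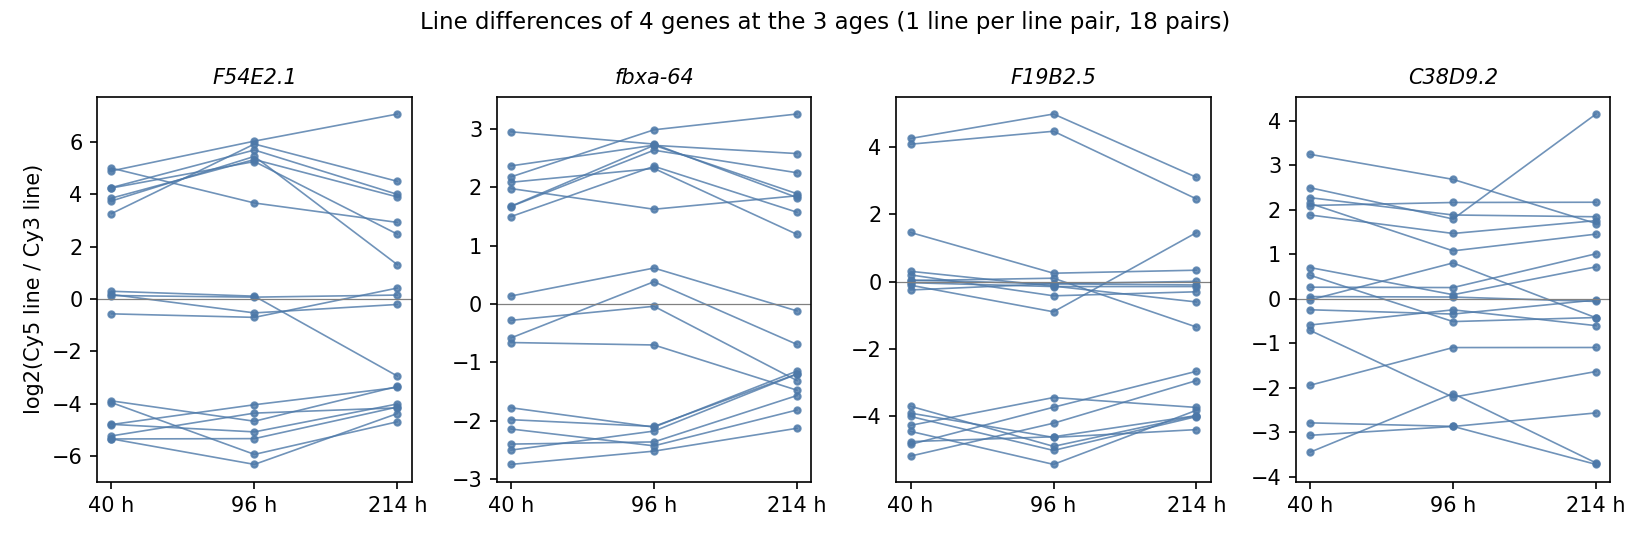
Log2 ratio of the Cy5 line over the Cy3 line for F54E2.1, fbxa-64, F19B2.5 and C38D9.2 at 40 h, 96 h and 214 h, 1 line per pair of lines (18 pairs). Most pairs keep their side and their order between ages, with r from 0.91 to 0.98.

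The labels name 35 distinct lines where the growth protocol counts 36, because WN19 is given for the Cy3 channel of 2 arrays at each age. After removal of the age means, the Cy3 values of these arrays correlated across genes with r = -0.07 at 40 h, -0.02 at 96 h and 0.09 at 214 h. They ranked 82nd, 60th and 35th among all pairs of arrays of their age. Over the 676 genes with lasting differences, r was -0.22, -0.14 and -0.10. The same array position compared between ages gave a median r from 0.52 to 0.61 over these genes, and different positions a median r from -0.03 to -0.02. These genes were chosen because pairs agree between ages on the same arrays. That choice raises the r of the same position, which is therefore no independent reference for the WN19 samples. Genes are not independent replicates, and no comparison above uses a line's name other than to pair the arrays.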

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

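Of the tests in this part, all counts of splits, all tests on what the WN76 sample is, the tests on the E. coli spots, the fits without the WN76/WN59 pair or with the age changes regressed out, and the tests on larvae and on scaling for the sperm genes were chosen after the result was seen.

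The Cy3 sample labelled WN76 at 214 h lay at 0.08 on the axis of age, among the larvae (-0.125 to 0.218) and below its Cy5 partner on the array, WN59 (0.717), which itself lay below all other samples of 214 h (0.851 or above). Its col genes stood at 0.69 and its muscle genes at 0.25 relative to the mean of 40 h, where the Cy5 sample of the same array stood at -2.21 and -1.77. Slow ageing of the line and an exchange with its own larval sample are argued against by the WN76 samples of 96 h and 40 h, which lay at 0.665 and -0.021, inside the ranges of their ages. Larvae of the same line are argued against by its line profile over lasting genes, which correlated with WN76 at 40 h with r = 0.198, below the lowest r of any other Cy3 line with itself between 40 h and 214 h, on genes chosen without that line (0.297, WN20). The label of that WN20 sample of 214 h is itself doubtful, since it matched WN76 (r = 0.442) better than WN20 (0.293). The median r of the other lines with themselves was 0.521, and the 95th percentile of r between different lines 0.287. RNA of another line harvested at 40 h is a candidate explanation that stays open, since r was 0.702 with the WN19 sample of the WN19/WN39 array at 40 h and at most 0.119 with any other line apart from WN76, and since the sample numbers of both differ in 1 digit, as do 2 of the 96 numbers given.

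The SD of line differences was higher at 214 h than at 40 h, with a median over genes of the log2 ratio of both SDs of 0.27. Without the WN76/WN59 pair the value was 0.174 (SD of permuted values 0.0991), which decides neither way whether that array is the cause. A lower level of the genes themselves does not account for the value in genes of equal mean intensity at both ages (1909 genes, 0.228, permuted SD 0.0978, WN76/WN59 pair kept). Quantile scaling between arrays preceded that choice of genes, so that they cannot decide on lower signal of whole arrays. Worm probes clear of background went from 44% at 40 h to 41% at 214 h in Cy3 and from 49.8% to 41.9% in Cy5. For lines at different points along the age axis, the age changes were regressed out. The value was then 0.201 (permuted SD 0.0974, permutation p = 0.04), and the genes more spread numbered 285 in place of 914. That fit kept the WN76/WN59 pair, and the pair was not left out and the age changes regressed out together. It therefore cannot decide whether different points along the axis account for the whole. A greater divergence of inbred lines in old age may remain, as may array noise, since between probes of the same gene both the shared variance of log ratios (0.0704 at 40 h and 0.11 at 214 h) and the unshared variance (0.0695 and 0.0978) were higher at 214 h.

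Sperm genes, which fell from 40 h to 96 h, were higher at 214 h than at 96 h by a median of 1.48 on the log2 scale. The WN76 sample is argued against as the cause, because 29 of 33 sperm genes were still called higher without its pair. Larvae in the old samples, if like those of 40 h, are argued against by 485 other genes, whose median change to 214 h was 0.15 (quartiles -0.21 and 0.76). These genes were chosen for a fall of at least 4-fold from 40 h to 96 h, so that they cannot decide on larvae of other stages. Scaling and background correction are argued against by the lower of the relative medians under both alternatives, 1.19 against 1.40. A change of the germ line in old hermaphrodites, or males among the old worms, could remain, and neither was tested. Nor can age be told from the time since FUDR, which differs between 96 h and 214 h.

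Spots for E. coli sequences, which no comparison uses, stood above empty spots, with a mean log2 foreground over background of 0.858 over 54 arrays. The means of the 18 spots were 0.90 ± 0.25 (SD, n = 18 arrays) at 40 h, 1.02 ± 0.14 at 96 h and 0.65 ± 0.18 at 214 h, against 0.10, 0.09 and 0.10 for 619 empty spots. The median over worm probes on the same scale was 0.62, 0.53 and 0.44, lower at each later age, and the E. coli spots were not tested relative to it. From 96 h to 214 h they fell by 0.37 in 17 of 18 pairs (permutation test with 100000 resamples, adjusted p = 0.00012), and from 40 h to 214 h by 0.25 in 14 of 18 (adjusted p = 0.01). From 40 h to 96 h the difference of 0.12 did not pass (adjusted p = 0.1).

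Chance can be excluded at 1 in 20 for each count of genes, because with ages permuted within pairs only the real arrangement, 1 of 100, gave as many. The counts of 4649 higher and 3400 lower genes from 40 h to 96 h compare with 1325 and 1640 at most in the other draws. From 96 h to 214 h, 3938 and 3442 compare with 1841 and 2598, and from 40 h to 214 h, 4952 and 4051 with 823 and 764. For spread, 123 more and 261 less at 96 h than at 40 h compare with 46 and 1. At 214 h against 96 h, 447 and 92 compare with 2 and 0, and at 214 h against 40 h, 914 and 372 with 1 and 1. For the 676 lasting line differences, with pairs exchanged between ages, the highest other draw gave 1. The median SD ratios ran in the other draws from -0.29 to 0.36 (214 h over 96 h, real 0.30) and from -0.36 to 0.26 (214 h over 40 h, real 0.27), so that some draws exceeded the real values in size.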

How the results depend on the processing

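The alternatives without the WN76/WN59 pair or with the age changes regressed out, those for gene lists and families apart from the estimated correlation, and the label check on lasting genes were chosen after seeing the data. Of 216 values set against alternatives, 155 kept their call or, for counts, about their size, 48 counts moved, 12 lost a call, 1 gained one and 0 were called in the opposite direction. Counts passed as about their size even where 3400 lower genes from 40 h to 96 h became 2471 with arrays centred. The same holds for 447 genes more spread at 214 h than at 96 h, which became 308 without the WN76/WN59 pair. SD ratios and correlations were compared by their call alone, and values without a call did change sign or size. The SD ratio of 96 h over 40 h, -0.01, was 0.31 with median centring of the ratios, 0.08 on a common scale and 0.03 with the strict filter, the median correlation of 96 h and 214 h went from 0.04 to 0.15 with median centring, and the correlation of both WN19 samples at 214 h went from 0.09 over all genes to -0.10 over lasting ones. Leaving out the replicate block gave 4493 higher and 3296 lower genes from 40 h to 96 h, 3716 and 3325 from 96 h to 214 h, and 4827 and 3937 from 40 h to 214 h. Apart from the strict filter and the 2-fold limit, these counts ran from 4410 to 5886 and 2471 to 4367, from 3660 to 4896 and 3280 to 4290, and from 4818 to 6360 and 3477 to 5152. The authors' table holds log ratios, so that it was not run for these counts. The median correlation between 40 h and 214 h stayed between 0.14 and 0.23 with a call.

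The strict filter left 2622 genes, the brightest, and gave 1251 higher and 520 lower genes from 40 h to 96 h, 1062 and 469 from 96 h to 214 h, and 1495 and 586 from 40 h to 214 h. More and less spread then were 2 and 34, 232 and 4, and 335 and 92 genes, the SD ratios 0.312 (214 h over 96 h) and 0.334 (214 h over 40 h), both without a call, and lasting differences 77 genes and 0 lists. Fewer genes tested lower the counts by construction, and the cause of the lost calls was not tested. The limit of 2-fold took subsets of 1384 and 1397, 523 and 1111, and 2229 and 1986 genes. No filter, with 18880 genes tested, gave 207 and 403 genes more and less spread at 96 h than at 40 h, 142 less spread at 214 h than at 96 h and 575 than at 40 h, and SD ratios of 0.166 and 0.137, which lost their calls for a cause not tested. Leaving out the arrays of 40 h, 96 h or 214 h, with fewer arrays, gave 230, 291 and 375 lasting differences.

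For the other changes the cause was not tested. Without background correction 225 and 474 genes were more and less spread at 96 h than at 40 h, and the SD ratios 0.307 and 0.265 lost their calls. With median centring of the ratios 79 genes were less spread at 96 h than at 40 h, 141 more and 57 less at 214 h than at 96 h, and 147 less at 214 h than at 40 h, and the SD ratio 0.23 of 214 h over 96 h lost its call, while that of 214 h over 40 h was 0.55 (permutation p = 0.01). Without the pairs with doubtful labels 71 and 110 were more and less spread at 96 h, 281 more at 214 h than at 96 h and 203 less than at 40 h, and the SD ratios 0.314 and 0.278 lost their calls. The authors' log ratios gave 226 and 489 at 96 h, and an SD ratio of 0.269 (214 h over 40 h) without a call. Without the WN76/WN59 pair 596 genes were less spread at 214 h than at 40 h, and the SD ratios 0.182 and 0.174 lost their calls. With the age changes regressed out 103 genes were more spread at 214 h than at 96 h, 285 more and 189 less than at 40 h, and the median correlation of 96 h and 214 h, 0.11, gained a call. An F test of variances gave 319 and 578 at 96 h, 927 more at 214 h than at 96 h and 1476 more than at 40 h. Of the 46 list calls 1 held with an estimated correlation.

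Of 375 changes of named genes, 11 lost their call with centring and 1 was reversed, rpl-22 from 40 h to 96 h (0.13, adjusted p = 0.518). Leaving out the replicate block ended 2 calls, no background correction 1, no filter 2, separate channels 2, the doubtful pairs 3, scan day as the block 2, array weights 1 and the WN76/WN59 pair 3. The strict filter left 271 untested and ended none of the others.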

Other observations

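The tests on neighbouring genes and on the likeness of WN27 to WN19 and of WN20 to WN76 were chosen after the result was seen.

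Some lists without a camera call held members that moved far apart with age. Among histone genes, 15 of 32 were higher and 9 lower at 214 h than at 96 h, the linker histone gene hil-7 rising 3.01-fold (log2 change 1.59 ± 0.12 SE, n = 18 pairs), while his-41 fell 2.97-fold and his-35 2.63-fold. From 40 h to 214 h, hil-7 (3.10-fold) and hil-4 (2.83-fold) rose, and his-71 (3.30-fold) and his-2 (3.10-fold) fell. Of the DAF-16 targets, lea-1 rose 6.00-fold and mtl-1 4.79-fold from 40 h to 214 h, against falls of gpd-2 (5.48-fold) and pck-1 (5.39-fold). In innate immunity, the lysozyme gene ilys-3 was 8.32-fold higher at 214 h than at 40 h, and lys-4 was 7.04-fold and dod-17 8.22-fold lower. The glutathione S-transferase genes gst-26 and gst-10 fell 9.34-fold and 5.66-fold over the same span, in a list of antioxidant and phase II genes with 14 higher and 19 lower of 39. Of 18 chaperone genes 5 were lower and 2 higher, among them hsp-3 (3.20-fold lower) and the disulfide isomerase genes pdi-2 and pdi-6 (3.05-fold and 2.90-fold lower). Heterochronic regulators of larval development were measured for 5 genes, of which lin-29 fell 2.65-fold and lep-2 rose 2.26-fold by 214 h. Of 54 chemoreceptor genes 20 were higher and 20 lower, srlf-4 by 7.49-fold and srm-3 by 7.13-fold lower.

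In spread between lines, 29 of 155 F-box and MATH genes were more spread and 9 less at 214 h than at 40 h, and 18 were more spread and 3 less at 96 h than at 40 h. Respiration genes were more spread in 10 of 36 cases and less in 2 (median SD 0.20 at 40 h and 0.34 at 214 h). The gene nspd-7 was least spread at 96 h (SD 3.24 at 40 h, 1.51 at 96 h and 3.55 at 214 h), and pud-4 went from 4.86 at 96 h to 3.14 at 214 h.

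Genes with lasting line differences that lie close together tended to differ between the same lines. Over 195 pairs of such genes at most 5 genes apart, the median absolute r of their line pair means was 0.781, against 0.209 for pairs on different chromosomes and at most 0.26 in 1000 draws of such pairs. For the 156 neighbouring pairs whose names do not share a family it was 0.724. A local genetic difference shared by neighbours, as an inherited block of either parent would give, may account for this, although genotypes were not used here and hybridisation between related sequences was not excluded.

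The Cy3 sample labelled WN19 on the WN19/WN1 array resembled the sample labelled WN27 over the lasting genes, with r = 0.688 at 40 h and 0.759 at 96 h, the highest among all pairs of arrays of their age. At 214 h r was 0.188, which ranked 17th. Over all arrays, 4 channels matched the profile of another label better than their own. They were WN27 at 96 h, which matched that WN19 sample, WN76 at 214 h, WN76 at 96 h (r = 0.231 with WN20 and 0.224 with its own label) and WN20 at 214 h (r = 0.442 with WN76 and 0.293 with its own label). On genes chosen without both pairs, the WN20 sample of 214 h correlated with WN76 at 40 h and 96 h with r = 0.381 and 0.379, and with WN20 with r = 0.297 and 0.225. The WN76 samples of 40 h and 96 h correlated with each other with r = 0.446.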
